A study of Mus musculus with 10 samples.

How the data were processed

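The 10 samples were total RNA of 3T3-L1 cultures, extracted with Trizol, labelled with biotin from 15 ug of RNA and hybridised to Affymetrix arrays, per the labels. They formed 4 groups: CLA at 8 h (1 array), CLA at 12 h (1 array), LA at 8 h (4 arrays) and LA at 12 h (4 arrays). The deposited value table holds a probe set intensity per array on a linear scale; 22.5% of its values are at or below 0, so a background was subtracted, and its software and scaling are not stated. The authors also deposited a table pooled over both times with a ratio and its fold change, a log10 ratio with its log10 error, and a p-value for each probe set. How the authors pooled the arrays behind each ratio and which error model gave the deposited p-value are not stated.

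Of 45101 probe sets, 64 array controls were left out. Probe sets with exactly 1 gene symbol (34945) were used, 932 with several and 9160 with none were not, and 34741 symbols were brought up to date through the Entrez identifier. The medians of the arrays differed by more than 0.1 on the log2 scale, so the values were quantile normalized, raised to a floor and put on the log2 scale. The floor planned before the data were examined, the 10th percentile of the table, is negative (-4.56) and has no logarithm. The floor used instead was the size of the 2nd percentile of the table, 14.3, chosen after the range of the values was seen and before any comparison was fitted. The number of genes called depends on this floor. The brightest probe set by mean log2 value stood for each of 18193 genes, and the lowest 40% by mean log2 value (7277) were left out, which left 10916; 11.1% of their values lay at the floor.

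Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a variance trend, two-sided, Benjamini-Hochberg over the genes tested, called at an adjusted p under 0.05). CLA against LA over both times was an additive fit of treatment and time to all arrays. The comparisons at 8 h and at 12 h, the interaction and the LA time comparison came from a fit of 4 group means, whose spread comes from LA arrays alone; the lone CLA array at each time is assumed to vary like them. Gene lists fixed before the data were examined (26, of which 25 had at least 5 tested genes) were tested with camera at a preset correlation of 0.01 and again with a correlation estimated per list. Camera compares a list with the other genes tested, so its direction is relative to them and not to 0. The genes named are, by a rule set at the same time, 20 always-named genes, the genes passing in each direction with the 5 smallest p where fewer than 10 passed, and up to 4 members of each list named. The smallest p were taken among genes whose CLA array lay on the same side of the LA mean at both times. Correlations across genes use genes that are not independent replicates.

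Replicate numbers were tested as a pairing of the LA arrays at 8 h and 12 h. After the mean of each time was removed, arrays of the same number correlated across genes at 0.855, 0.779, 0.503 and 0.553 for numbers 1 to 4, above the highest correlation with another number (-0.124, 0.238, 0.283 and 0.113). The numbers were therefore used as a block in a further fit. LA replicate numbers were also compared with each other, by arrays and with the mean of the 2 arrays of each number as 1 unit. In the latter the spread comes from the other 3 numbers alone, and the lone number is assumed to vary like them. Spearman correlations between arrays over all probe sets ranged from 0.733 to 0.912. The number of arrays and their replicate structure limit the precision: the median half-width of the 95% interval for CLA against LA over both times was 0.89 on the log2 scale, or 0.65 with the block.

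The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold at once among 10916. The simulated arrays carried the replicate differences measured in the LA arrays, which favours the fit with the block. The changed genes left out the dimmest, the noise was independent between genes and no floor was applied. The shares recovered may therefore not hold for the real data. For CLA against LA over both times, 1% of 2-fold and 47% of 4-fold changes were recovered without the block (0 false calls), and 38% and 98% with it (14 false calls). At 8 h and at 12 h, 0% of 2-fold and of 4-fold changes were recovered without the block; with it, 78% and 68% of 4-fold changes were (8 and 6 false calls). For LA over time the 4-fold share was 34% (0 false calls), or 98% with the block (9 false calls). Alternatives were other scalings, floors, filters, probe set rules and variance settings, the block, the estimated correlation, each array left out in turn, fits of fewer arrays and the authors' table. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.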

Results

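Expression was profiled on 10 Affymetrix arrays in cultures of 3T3-L1 adipocytes, a mouse fibroblast line that can be differentiated into fat-storing cells. The cultures received either c9t11 CLA, a conjugated linoleic acid with a cis double bond at carbon 9 and a trans double bond at carbon 11, or the control LA. LA is the usual short name of linoleic acid, a related fatty acid whose double bonds are both cis and not conjugated, although the labels do not spell it out. RNA was taken at 8 h and 12 h. The LA groups held 4 arrays at each time, labelled biological replicates 1 to 4, and the CLA groups held 1 array at each time, both labelled biological replicate 1. For arrays, the number of arrays limits the precision, and no CLA value has a replicate of its own. Of 18193 genes with a probe set, 10916 were bright enough to be tested.

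The arrays fell apart by replicate number more than by fatty acid or time. The first principal component held 65.3% of the variance, and the 4 arrays numbered replicate 1 (both CLA arrays and an LA array from each time) scored -75.9 to -40.9 on it, against 24.7 to 73.6 for the 6 LA arrays numbered 2 to 4. The replicate 1 arrays were also dimmer, with 75th percentiles of intensity of 26.4 to 39.5 against 54.4 to 76.8. Differences between CLA and LA are therefore given with the replicate number as a block as well, which sets each CLA array mainly against the LA array of replicate 1 at the same time.

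**Figure D1:**
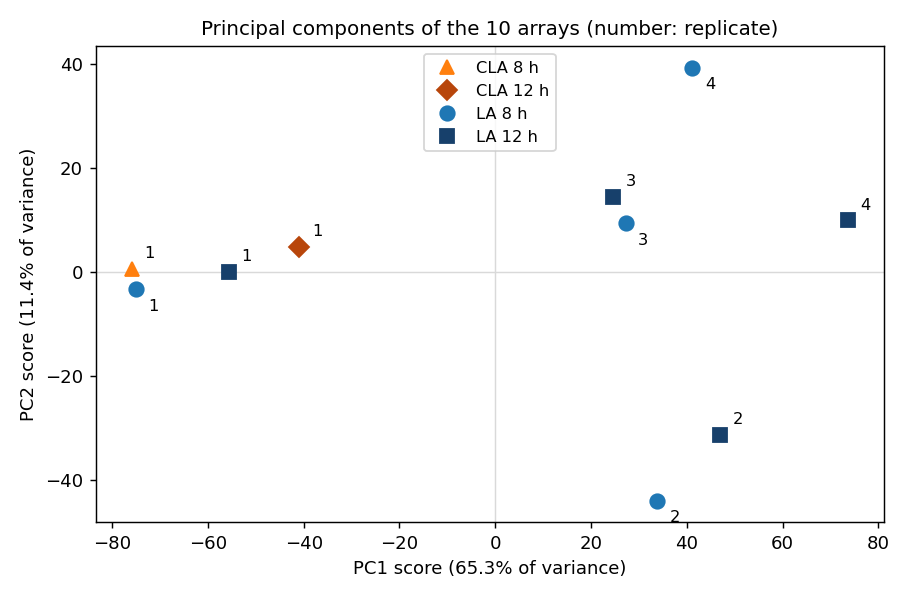
Scores of the 10 arrays on the first and second principal components of the log2 values, as percent of variance on each axis; each point is an array, with its colour and shape giving the fatty acid and time and the number beside it the replicate. The 4 replicate 1 arrays lie between -75.9 and -40.9 on the first component and the other LA arrays between 24.7 and 73.6.

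The main comparison asked how transcripts differed between CLA and LA cultures over both times. Pparg, the main regulator of fat cell formation, differed by -0.21 (SE 0.29), and Fasn, the fatty acid synthase, by 0.11 (SE 0.45). Adipoq, which encodes the hormone adiponectin, was at log2 12.94 ± 0.20 (SD, n = 4) in LA at 8 h and 12.90 in the CLA array, and differed by 0.04 (SE 0.19) over both times; Fabp4, a fatty acid carrier, differed by 0.05 (SE 0.18) and Scd1, the stearoyl-CoA desaturase, by 0.20 (SE 0.31). These 3 genes were among the 10 brightest tested genes in 9, 10 and 8 of the 10 arrays, where quantile normalization all but fixes the values, so a small difference there does not show that their levels were alike. Among the always-named genes, those of the ATF4 and oxidative stress lists stood further from LA. Trib3, a pseudokinase induced through the factor ATF4, was at 2.50 (SE 1.17) and Atf3 at 2.33 (SE 0.89). Hmox1, the heme oxygenase of the oxidative stress response, was at 1.68 (SE 0.70) and Ddit3 at 1.44 (SE 0.59). Cd36, a fatty acid transporter, was at -1.14 (SE 0.54). Stress genes did not all lie higher: of the 12 tested heat shock genes, 5 were higher and 7 lower in CLA. No gene passed the test: limma called 0 genes higher and 0 lower among the 10916, with the lowest adjusted p at 0.304 and 996 genes at an unadjusted p under 0.05, where 545.8 would be expected by chance. Chance would give the same 545.8 in each comparison of single genes below. With the replicate number as a block the count was 495, so the excess cannot be told from a replicate difference. The median of all tested genes lay at 0.15 (0.23 after median centring, -0.22 on the deposited scaling). Without LA replicate 1 of 12 h, Foxl2 (1.94) and Gm2762 (1.90) passed, and Gm2762 is named because it passed there, after its value was seen.

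With the replicate number as a block the ATF4 and oxidative stress genes named above came close to LA. Trib3 differed by 0.00 (95% interval -1.25 to 1.25), Atf3 by 0.17 (-0.65 to 0.98), Hmox1 by 0.05 (-0.74 to 0.85), Ddit3 by 0.26 (-0.26 to 0.77) and Cd36 by -0.30 (-1.28 to 0.68). Among the LA arrays alone and over both times, LA replicate 1 lay above LA replicates 2 to 4 by 3.34 for Trib3, 2.89 for Atf3, 2.17 for Hmox1 and 1.58 for Ddit3, and below them by a log2 difference of -1.12 for Cd36. Atf3 was at the floor in 4 of the 6 LA arrays of replicates 2 to 4, so the size of its difference depends on the floor. With each replicate number as 1 unit, limma gave an adjusted p of 0.0111 for Atf3, 0.0425 for Hmox1, 0.134 for Trib3, 0.176 for Ddit3 and 0.258 for Cd36; the spread comes from replicates 2 to 4 alone, and replicate 1 was picked after it was seen to stand apart. The block also gave 0 genes, with 495 at an unadjusted p under 0.05 and the lowest adjusted p at 0.656. Across genes, the differences from the fits with and without the block correlated at r = 0.101. The compounds are not shown to act alike: the median half-width of the 95% interval was 0.65 with the block, and for 66.2% of genes that interval excluded a difference of 2-fold or more. That share includes genes whose difference could not be measured. Lep was at the floor in every replicate 1 array, and Fabp4 was tied at the top of the scale within replicate 1 at each time.

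**Figure D2:**
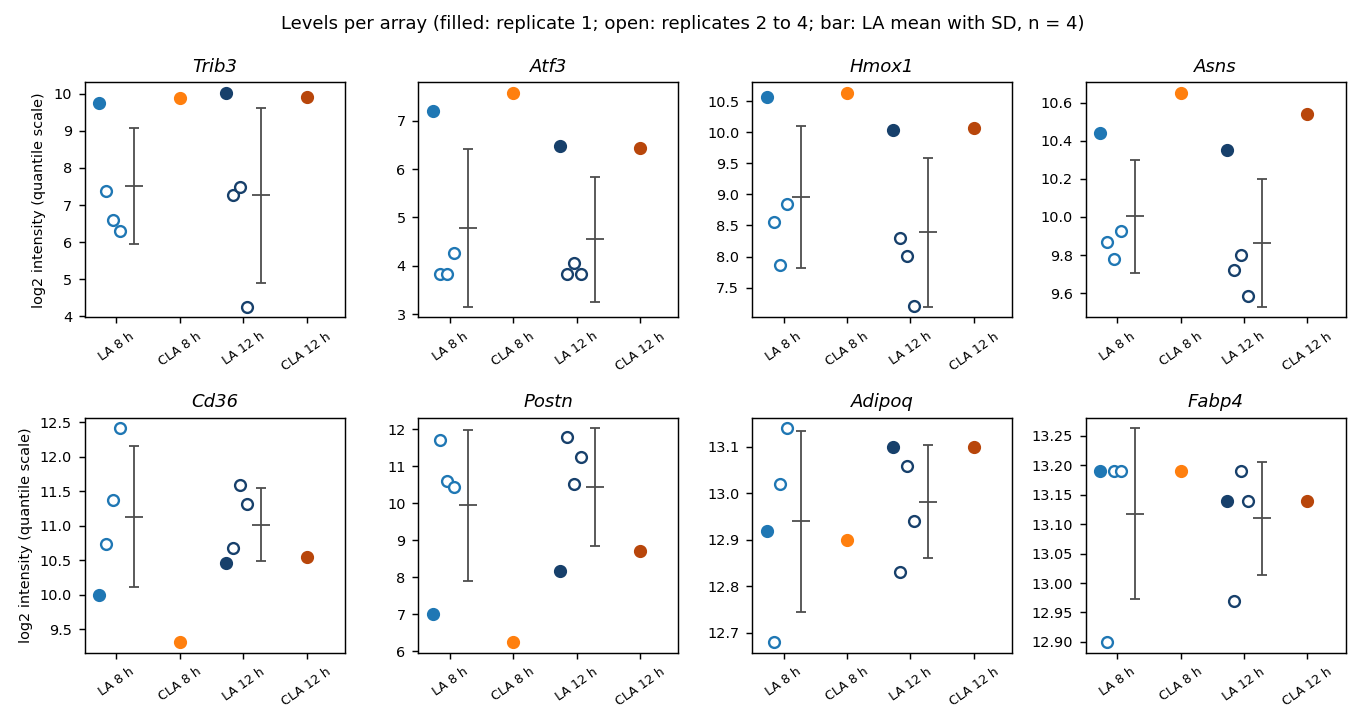
Log2 intensity on the quantile scale (vertical axes, which do not start at 0) of Trib3, Atf3, Hmox1, Asns, Cd36, Postn, Adipoq and Fabp4 in each array, by fatty acid and time; filled points are replicate 1, open points replicates 2 to 4, spread sideways in the order of their numbers, and the bar is the LA mean with its SD over 4 arrays. For Trib3, LA replicate 1 lay above replicates 2 to 4 by 3.34 over both times, and the CLA arrays (9.88 at 8 h and 9.90 at 12 h) lay near LA replicate 1.

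The other metabolic and inflammatory genes fixed for naming did not pass either. Angptl4, an inhibitor of lipoprotein lipase, was 1.16 (SE 0.52) from LA without the block and 0.06 (95% interval -0.53 to 0.65) with it. Asns, the asparagine synthetase, was at 0.66 (SE 0.26) and 0.20 (-0.16 to 0.57). Cebpa was at 0.61 (SE 0.52), Lpl at -0.33 (SE 0.26), Cpt1a at 0.42 (SE 0.34), Pdk4 at 0.45 (SE 0.36), Ccl2 at -0.67 (SE 1.09) and Lep at -0.21 (SE 0.39), the last with 7 of 8 LA arrays at the floor. After median centring Pparg (0.09), Lpl (0.14) and Lep (0.19) lay on the other side of 0. Il6 and Ptgs2 were too dim to be tested. Of the 8 always-named genes with several bright probe sets, 5 had the same sign in each, and Fabp4 (-0.93 to 0.05), Cpt1a (-0.37 to 0.42) and Ddit3 (-0.43 to 1.44) had probe sets on both sides of 0.

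None of the genes with the smallest p passed, and those higher in CLA were dim. Only genes whose CLA array lay on the same side of the LA mean at both times were ranked, so that agreement was fixed by the choice. Isoc2b was higher in CLA by 1.43 (SE 0.21), Foxl2 by 1.80 (SE 0.29), Fam151a by 1.21 (SE 0.21), Cox6b2 by 1.45 (SE 0.26) and Stbd1 by 1.13 (SE 0.21), with 4 to 8 of the 8 LA arrays at the floor. Aqr, an RNA helicase, was lower by a log2 difference of -1.78 (SE 0.38), Sltm of -2.05 (SE 0.51), Tbc1d8b of -2.60 (SE 0.70), Ift74 of -1.99 (SE 0.54) and Nsrp1 of -1.56 (SE 0.42), with 0 of the 8 LA arrays at the floor. In CLA, Nsrp1 was at the floor (log2 3.84) in 2 arrays and Ift74 in 1. Aqr (4.02 and 4.20), Tbc1d8b (4.06 and 4.25) and, at 8 h, Sltm (3.87) lay near it. These sizes, with or without the block, therefore depend on the floor as well. With the block Aqr was at -1.75 (95% interval -2.58 to -0.91), Isoc2b at 1.37 and Foxl2 at 1.40, while Sltm was at -1.11, Ift74 at -0.87, Nsrp1 at -0.76 and Tbc1d8b within an interval of -1.67 to -0.34. None of these genes passed with the block either. They were picked by their p in a fit of the same arrays, so an unadjusted interval that excludes 0 is no further evidence of a CLA effect.

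Of the 25 gene lists tested, camera with a preset correlation called 2 higher and 3 lower in CLA (11 and 3 on the deposited scaling, 6 and 2 after median centring). None of the 5 held with an estimated correlation (adjusted p = 0.838 for each). In the ATF4 and integrated stress response list, 26 of 29 tested genes were above LA, with a median of 0.66 (adjusted p = 0.00194), led by Trib3, Atf3, Ppp1r15a (2.07, SE 0.81) and Chac1 (1.93, SE 0.90). In the NRF2 list, which holds oxidative stress genes, 18 of 20 were above LA with a median of 0.78 (adjusted p = 0.00508), among them Hmox1 and Srxn1 (1.49, SE 0.49). The cell cycle list had 20 of 23 genes below LA, with a median of -0.65 (adjusted p = 0.000625), such as the proliferation gene Mki67 (-2.00, SE 0.90) and the topoisomerase Top2a (-1.87, SE 0.86). Mki67 was at the floor in 2 CLA arrays and Top2a in 1, so the sizes of these differences depend on the floor. The extracellular matrix list had a median of -0.37 (adjusted p = 0.000869), with Postn at -2.70 (SE 1.10) and the collagen cross-linking enzyme Lox at -2.36 (SE 0.98). All 13 tested preadipocyte and fibroblast markers lay below LA, with a median of -0.85 (adjusted p = 0.000625), and Postn is in this list and in the matrix list. No member of any list passed: limma called 0 over all genes tested and 0 adjusted over the list alone. The lists not called had adjusted p from 0.0825 (fatty acid oxidation, median 0.46) to 0.883 (inflammation and NF-kB targets). For the endoplasmic reticulum chaperone, inflammation and ribosomal protein lists the median, the mean and the test differed in sign. The sign of the test is relative to the other genes tested, and the median of all tested genes was 0.15. Among the cell type markers, the 5 tested white adipocyte genes, among them Adipoq and Fabp4 at the top of the scale, had a median of 0.04, the 5 macrophage markers 0.61 (adjusted p = 0.376), and the 4 muscle and brown adipocyte markers, too few to test, 1.54.

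These list calls moved with the replicate number. With the block, 0 lists were called (lowest adjusted p = 0.580), and the medians became 0.05 for the ATF4 list, 0.05 for the NRF2 list, 0.19 for cell cycle, -0.09 for extracellular matrix and -0.06 for preadipocyte and fibroblast markers. LA replicate 1 lay on the same side of LA replicates 2 to 4 with medians of 0.92, 0.90, -1.30, -0.55 and -1.10 for the same lists. Without the CLA array of 8 h, 10 lists were called. On simulated data with 1 list shifted by 0.5, camera also called 4 of the 24 other lists without the block and 0 with it. Those data were built with the measured LA replicate differences and with both CLA arrays as replicate 1. The outcome was therefore largely built in and adds no evidence on the cause.

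**Figure D3:**
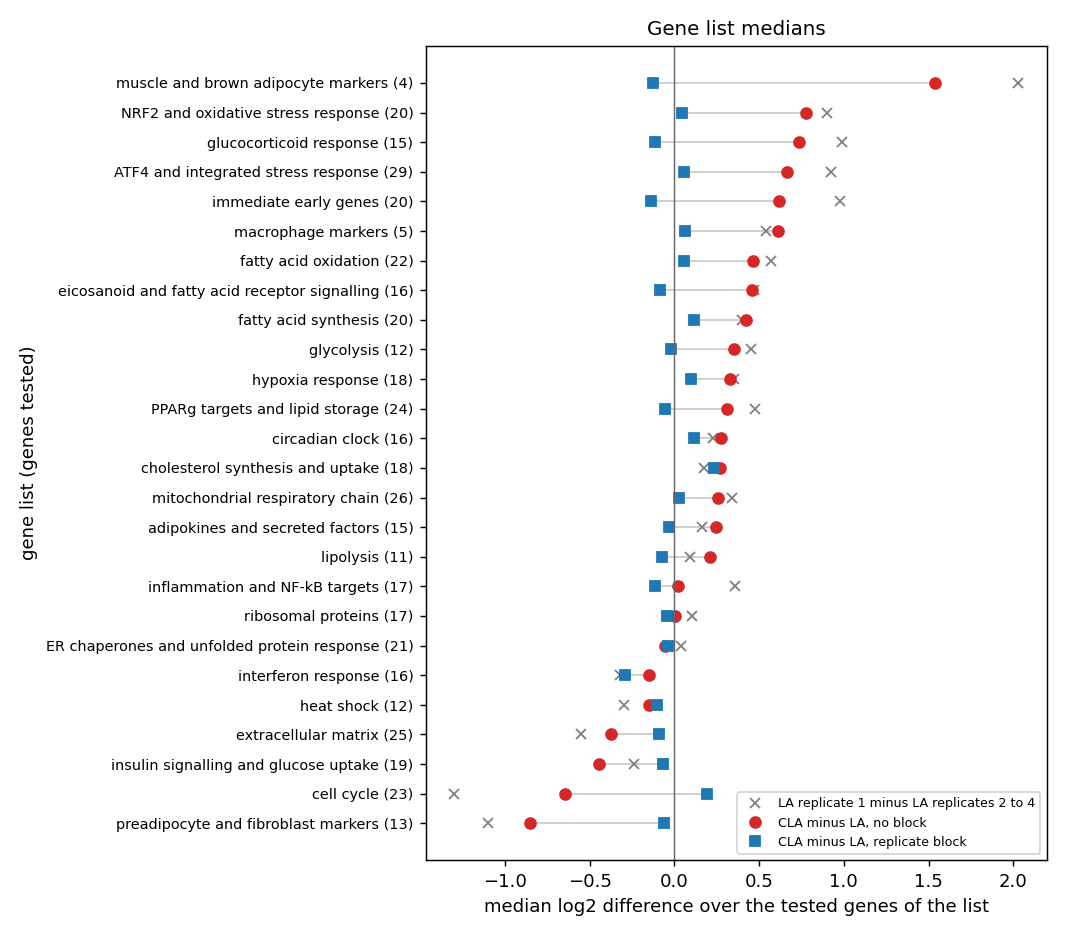
Median log2 difference over the tested genes of each of the 26 gene lists (number of genes in brackets): CLA minus LA without a block (circles), CLA minus LA with the replicate block (squares), and LA replicate 1 minus LA replicates 2 to 4 (crosses). The median of the ATF4 list is 0.66 without the block, 0.05 with it, and 0.92 between the LA replicates.

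The authors' deposited table gives a ratio and a p-value for each probe set, pooled over both times; its direction was read from the value table, against which it runs as CLA over LA across genes (r = 0.914 with the difference without the block, from the same arrays). Of the 45037 probe sets in the authors' deposited table, 6446 had a p under 0.05, 1960 with a ratio above 1 and 4486 below. Over the tested genes, 513 of the p-values in the authors' deposited table stayed under 0.05 after Benjamini-Hochberg adjustment. The authors' deposited table put Trib3 at a ratio of 3.08, Atf3 at 5.32, Hmox1 at 2.81 and Cd36 at 0.462. Its unadjusted p-values for them were 0.0686, 0.00563, 0.0123 and 0.0368, so Trib3 was not under 0.05. Across genes the log ratio of the authors' deposited table had r = -0.0155 with the difference within replicate 1.

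At 8 h alone, the single CLA array was set against 4 LA arrays. Pparg was at 9.98 in the CLA array against 10.19 ± 0.40 (SD, n = 4) in LA, and Lpl, the lipoprotein lipase, at 11.95 against 12.69 ± 0.37. Within replicate 1, Trib3 differed by 0.11, Atf3 by 0.37, Cd36 by -0.69 and Hmox1 by 0.08. No gene passed in limma, without the block (488 genes at an unadjusted p under 0.05, lowest adjusted p 0.199) or with it (647 genes, 0.569). The lone CLA array is assumed to vary like the LA arrays, and without LA replicate 1 of 8 h the count became 102, with 100 higher and 2 lower in CLA. With the replicate number as a random block, 13 genes were called, all higher in CLA, among them Elovl7 (1.68) and Smpd3 (1.54), chosen here after their values were seen and each at the floor in all 4 LA arrays at 8 h.

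At 12 h alone, Pparg was at 9.77 in the CLA array against 9.97 ± 0.37 (SD, n = 4) in LA, and Lpl at 12.85 against 12.79 ± 0.15. Within replicate 1, Trib3 differed by -0.12, Atf3 by -0.04, Cd36 by 0.09 and Hmox1 by 0.03. Limma called 0 genes, with 186 at an unadjusted p under 0.05 and the lowest adjusted p at 0.927, or with the block 636 and 0.823. A fit of the 5 arrays of 12 h alone called 67 genes, all higher in CLA. The difference between the CLA responses at 12 h and 8 h was tested as an interaction: 0 genes passed, with 116 at an unadjusted p under 0.05, or 729 with the block. Across genes, the differences within replicate 1 at 8 h and at 12 h, which share no array, correlated at r = 0.00453.

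The change of the LA cultures from 8 h to 12 h was compared over 4 arrays at each time, and none of its list shifts held with an estimated correlation (lowest adjusted p = 0.657). Cell cycle genes lay higher at 12 h as a list, 21 of 23 of them, with a median of 0.40 that pair 4 carried (1.90, against 0.00, 0.12 and -0.16 in pairs 1 to 3), including the helicase component Mcm5 at 1.16 (SE 0.78) and Rrm2, a ribonucleotide reductase subunit, at 1.03 (SE 0.98). Hypoxia response genes lay lower, with a median of -0.37 that pair 4 carried as well (-1.20, against -0.21, 0.12 and 0.10 in pairs 1 to 3), including Ankrd37 at -0.94 (SE 0.69) and Adm, which encodes adrenomedullin, at -0.75 (SE 0.35), both higher at 12 h in 0 of 4 pairs, and Bnip3 at -0.50 (SE 0.37), higher in 2 of 4. Glycolysis genes lay lower with a median of -0.29, such as Pfkl at -0.72 (SE 0.69) and Tpi1 at -0.44 (SE 0.27), both higher at 12 h in 0 of 4 pairs. The glycolysis median was -0.13, -0.20, 0.02 and -0.77 in pairs 1 to 4, lower in 3 of 4. No single gene passed in limma: 0 higher and 0 lower, with 26 at an unadjusted p under 0.05, and 0 with the block, with 457. Both counts lie below the 545.8 expected by chance. Without the block the differences between the pairs enter the spread, so the 26 does not show that little changed.

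Camera with a preset correlation called 11 of the 25 lists in the LA time comparison, 3 higher and 8 lower at 12 h. Cell cycle (adjusted p = 1.71e-06), extracellular matrix (median 0.20, adjusted p = 0.000226) and preadipocyte and fibroblast markers (median 0.31, adjusted p = 0.0122) were the lists that stood higher. Glycolysis (adjusted p = 0.000556), hypoxia response (adjusted p = 0.000901), the mitochondrial respiratory chain (median -0.15, adjusted p = 0.00247), fatty acid oxidation (median -0.18, adjusted p = 0.0140), fatty acid synthesis (median -0.29, adjusted p = 0.0140), PPARg targets and lipid storage (median -0.23, adjusted p = 0.0176), adipokines (median -0.26, adjusted p = 0.0195) and circadian clock genes (median -0.19, adjusted p = 0.0195) stood lower. No member passed, over all genes or adjusted over the list alone, and the median, mean and test differed in sign for the lipolysis and glucocorticoid lists. With the block 9 lists were called, 8 of them also called without it, and none held with an estimated correlation (lowest adjusted p = 0.810); PPARg targets (adjusted p = 0.0558), fatty acid synthesis (0.0865) and the clock list (0.151) no longer passed.

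The time lists differed between the LA pairs. Less the median of all genes in each pair, the fatty acid synthesis median was -1.55 in pair 4, against 0.17, 0.13 and 0.04 in pairs 1 to 3. The 12 h array of pair 4 also had a beta-actin 3' to 5' probe set ratio of 5.67, where the other arrays of that group had 1.49 to 1.73. Without that array 4 lists were called, 1 of them among the 11; without LA replicate 1 of 8 h there were 2, without LA replicate 4 of 8 h 5, and without LA replicate 2 of 12 h 4.

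**Figure D4:**
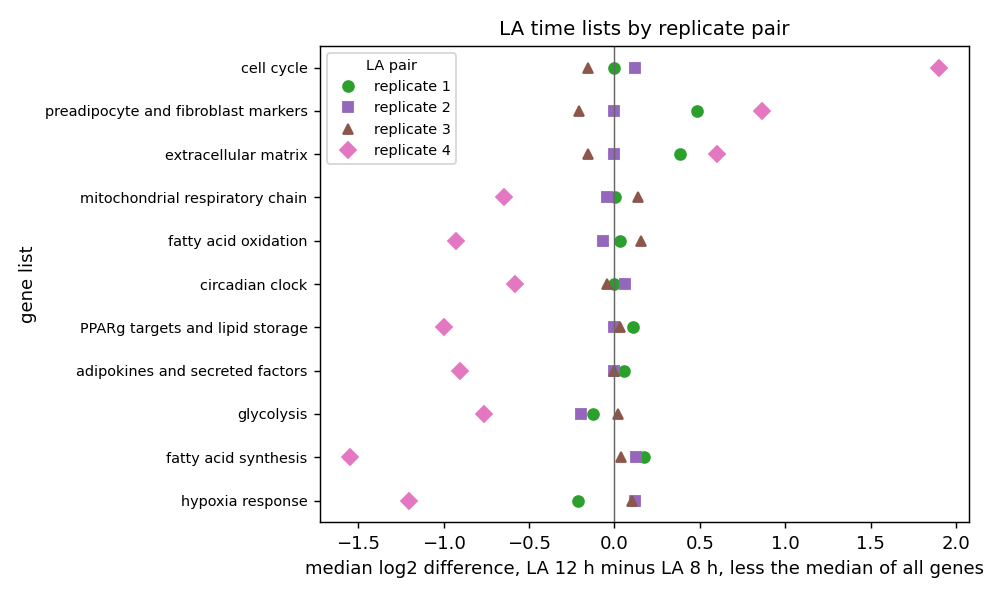
Median log2 difference between LA at 12 h and LA at 8 h over the tested genes of each of the 11 called lists, less the median of all genes in that pair, for each of the 4 LA replicate pairs. In pair 4 the cell cycle median is 1.90 and the fatty acid synthesis median -1.55, while pairs 1 to 3 lie between -0.21 and 0.48 in the lists drawn.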

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

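The tests on the replicate number, on CLA as the whole cause, on the 3' to 5' ratios, on the single 12 h array, on the 4 LA pairs and on the splits for genes were chosen after the result was seen; those on genomic span, on dim signal and on the splits for gene lists were set before.

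The differences of CLA from LA without the block, such as Trib3 at 2.50 and Postn at -2.70, resembled those of LA replicate 1 from the other LA replicates. Across genes, which are not independent, CLA minus LA at 12 h correlated at 0.776 with LA replicate 1 minus replicates 2 to 4 at 8 h, and CLA minus LA at 8 h at 0.828 with the same LA difference at 12 h, with no array shared. This is consistent with a difference that both CLA arrays carry because they belong to the replicate 1 set. With the labels as given, CLA as the whole cause is argued against, since CLA alone would leave the LA replicates unrelated to CLA minus LA, and the lower correlation with LA replicate 1 minus the others was 0.776. CLA as a part of the cause stays open, as does a wrong label on both LA replicate 1 arrays.

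The replicate 1 arrays lay apart from the other LA arrays, and limma called 4013 of 10916 genes between LA replicate 1 and replicates 2 to 4 by arrays, which counts the arrays of a number as independent, or 960 with each number as 1 unit, where the spread comes from replicates 2 to 4 alone and replicate 1, picked because it stood apart, is assumed to vary like them. RNA degradation as the cause is argued against, since the 3 LA arrays of replicates 2 to 4 with a beta-actin 3' to 5' ratio between 1.37 and 1.92 scored 24.7 or more on the first component, where the highest replicate 1 array scored -40.9. A bias on genomic span alone is too, since 75.5% of the genes called by arrays stayed called after a trend on span was removed (rho of difference and span -0.316), as are noise and floor effects of dim signal, since 34.4% of the brightest 25% of genes were called by arrays, and 31.1% of the dimmest 25%. These shares hold for the calls by arrays only and were not taken with each number as 1 unit. A batch of culture, hybridisation or scanning stays open, since the labels give none. No biological explanation was tested.

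The 11 list shifts between LA at 8 h and 12 h, such as cell cycle at 0.40 and hypoxia response at -0.37, may rest largely on LA pair 4. The 12 h array of that pair had a beta-actin 3' to 5' ratio of 5.67. Without that array and with the block, 1 of the 11 lists, glycolysis, was still called in its direction and 6 turned. The block then leaves the 8 h array of pair 4 without a partner, so this test cannot single out the 12 h array. Without that 12 h array and without the block, 1 was still called in its direction and 0 turned. Without LA replicate 4 of 8 h and without the block, 3 were still called in their direction and 1 turned. A change with time shared by all pairs was not seen, since the medians of 0 of the 11 lists moved the called way in all 4 pairs. It is not excluded: the glycolysis medians were -0.13, -0.20, 0.02 and -0.77 in pairs 1 to 4, where only pair 3 lay the other way. Other arrays matter as well: without LA replicate 1 of 8 h, 2 lists were called. Whether the 12 h array of pair 4 differs by RNA quality or by the state of its culture stays open.

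In the LA time comparison limma called 0 genes, with 26 at an unadjusted p under 0.05, so all 35 of the 35 splits of the 8 LA arrays gave as many, which decides nothing. The highest other split gave 180 genes, which points to a structure of the samples; it is 1 of 3 splits that keep all pairs whole, and the other two gave 0 (limma, 2308 and 708 at an unadjusted p under 0.05). For the lists, 19 of 35 splits gave at least the real 11 and the highest other gave 16, so chance cannot be excluded. Among the 8 splits that part all 4 pairs as the real one does, every split gave at least the real 11 and the highest other gave 15. The real count was therefore not high among the splits that keep to the pairing.

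Single LA arrays stood far from the other arrays of their group in 15 of 59 measures. In 4 of these (Fam151a, Lep, Cox6b2 and Fabp4) the other 3 arrays were tied at the floor or at the top of the scale, which fixes the outcome. Of the 55 others, 11 remain, where chance gives about 5% and the measures share arrays. The measures also include genes picked for a small p in CLA against LA, among them Sltm, Tbc1d8b, Nsrp1 and Foxl2. That rate may not hold for such genes. At 8 h, replicate 1 had a 75th percentile of intensity of 26.4 (others 63.1 to 68.0), and log2 levels of 5.47 for Sltm, 4.68 for Tbc1d8b, 4.53 for Nsrp1 and 7.19 for Atf3. At 8 h, replicate 2 had 12.90 for Fabp4 and 12.63 for Scd1. At 8 h, replicate 4 had 10.78 for Pparg, 3.93 for Fam151a and 5.49 for Lep. At 12 h, replicate 1 had 4.72 for Foxl2, 4.24 for Cox6b2 and 6.48 for Atf3. At 12 h, replicate 4 had a beta-actin 3' to 5' ratio of 5.67 (others 1.49 to 1.73) and a Gapdh ratio of 1.42 (others 0.845 to 0.879).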

How the results depend on the processing

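The floors at the 10th percentile of positive values and at 4 times the floor used, the random block, the fit of the replicate 1 arrays alone, and the block combined with an estimated correlation or a left-out array were chosen after seeing the data. Counts below are for CLA against LA over both times, at 8 h, at 12 h, then for LA over time and for the interaction, where limma called 0 genes in each. Without the filter on dim genes they were 51, 548, 361, 1 (Tcaf2, 0.70) and 739; with every probe set tested 124, 1179, 661, 1 (Tcaf2) and 1358. With 4 times the floor they were 7, 112 and 25, and 63 for the interaction. With the mean over probe sets they were 10, 38 and 7, and 1 for the interaction (4933406C10Rik, -1.97). In these settings the calls of CLA against LA were higher in CLA, except 1 at 8 h with every probe set, and many had all LA arrays of the comparison at the floor: 21 of 51, 429 of 548 and 314 of 361 without the filter. With lower floors the calls of CLA against LA were lower in CLA. The smallest positive value gave 42 at 8 h, 7 at 12 h and 40 for the interaction; the 25th percentile gave 2 over both times (H3f3a -5.20, Zfp74 -4.92) and 2 at 8 h (Rprd1a -5.81, Ppp4r3a -6.48); the 10th percentile of positive values gave 2 at 8 h (Rprd1a -5.18, Ppp4r3a -4.87). These genes were named after their values were seen. The replicate 1 arrays alone gave 0 over both times (limma, 614 at an unadjusted p under 0.05), the random block 13 at 8 h, the 5 arrays at 12 h alone 67, and 513 genes passed in the authors' deposited table (73 higher, 440 lower). With each array left out, the counts ranged from 0 to 2 over both times (2 without LA replicate 1 of 12 h), 0 to 102 at 8 h (102 without LA replicate 1 of 8 h) and stayed at 0 in the others. The CLA lists (5) became 14 on the deposited scaling, 8 after median centring, 0 with the block, 0 with an estimated correlation and 0 with both, and 4 to 10 with an array left out (10 without the CLA array of 8 h). The LA time lists (11) became 9 with the block, 0 with an estimated correlation, 0 with the block and an estimated correlation together, 4 with the block and without LA replicate 4 of 12 h, and 2 to 13 with an array left out (2 without LA replicate 1 of 8 h). Of 178 named genes, 96 changed sign with the block. Over all tested genes the differences with and without the block had r = 0.101, so this count shows little relation and not a reversal. The sign has no meaning for genes at 0 with the block, such as Fabp4 and Lep. Signal over background is limited, with 11.1% of tested values at the floor; beyond the counts given, the cause was not tested.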

Other observations

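Everything here was chosen after its values were seen: the comparisons of replicate numbers among the 8 LA arrays were not planned. With each replicate number as 1 unit (the mean of its 8 h and 12 h arrays, 1 number against 3), limma called 679 genes higher and 281 lower in LA replicate 1; the spread comes from replicates 2 to 4 alone, and replicate 1, picked because it stood apart, is assumed to vary like them. Cops2 was at -2.49 (SE 0.19), Uba3 at -2.50 (SE 0.21) and the ubiquitin ligase Ube3a at -3.13 (SE 0.25). Egr3, an immediate early transcription factor, stood 2.80 higher and Sprr1a 2.40 higher, each with 5 of the 6 arrays of replicates 2 to 4 at the floor, so that these sizes depend on the floor. The lists below were tested by arrays, 2 against 6, which counts the arrays of a number as independent. The ATF4 list had a median of 0.92 (adjusted p = 0.0155), cell cycle of -1.30 (adjusted p = 0.000315) and immediate early genes of 0.98 (adjusted p = 0.0461). The adjusted p of each of these lists was 0.999 with an estimated correlation.

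For replicates 2, 3 and 4 limma called 0 genes with each number as 1 unit (197, 16 and 275 at an unadjusted p under 0.05). By arrays, replicate 2 had lower cholesterol synthesis (median -1.10, adjusted p = 4.32e-07) and fatty acid synthesis lists (median -0.88, adjusted p = 1.36e-06), together with higher extracellular matrix (median 0.54, adjusted p = 5.46e-08) and preadipocyte and fibroblast markers (median 0.96, adjusted p = 5.86e-06). With an estimated correlation the adjusted p of each was 0.433. The cell cycle list was higher in it as well (median 0.78, adjusted p = 3.24e-05, or adjusted p = 0.551 with an estimated correlation). Replicate 3 had a lower inflammation and NF-kB list (median -0.91, adjusted p = 4.01e-07, and adjusted p = 0.0432 with an estimated correlation). The camera p-values were adjusted over the lists of each replicate number alone and not over all replicate numbers compared. Replicate 4 had lower glucocorticoid response (median -1.52, adjusted p = 0.0885 with an estimated correlation) and ATF4 lists (median -0.83, adjusted p = 1.68e-08, or adjusted p = 0.419 with an estimated correlation). Its arrays had beta-actin 3' to 5' ratios of 2.60 at 8 h and 5.67 at 12 h, and the 8 h array of replicate 3 had 2.58.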
